A study of Streptococcus mutans with 8 samples.

How the data were processed

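RNA sequencing of Streptococcus mutans UA159, an oral bacterium, was analysed in 8 libraries. Cultures had grown for 2 h at 37 °C in 25% Todd-Hewitt broth, a rich meat-based medium, per the labels' protocols. The cultures held no additive, 0.1 wt% of intact human salivary MUC5B (the gel-forming mucin of saliva), 0.1 wt% of the glycans of that mucin, or 0.1 wt% of the glycans of porcine MUC5AC (a gel-forming mucin of the stomach), with 2 libraries in each of the 4 groups. The labels call the libraries of a group biological replicates. The p-values rest on the spread between replicates, estimated over all 4 groups, and it includes a split between replicates that is described in the Results. Per the labels' protocols, cells were broken with beads, genomic DNA was digested, ribosomal RNA was removed with a bacterial depletion kit, libraries were made with the KAPA RNA HyperPrep kit, and single-end reads of 40 nucleotides were sequenced on an Illumina HiSeq instrument.

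The deposited values were whole-number read counts per gene, not normalized, in 1 table for all libraries; the column totals differed between libraries. The aligner, the counting tool, its strand setting and its treatment of reads that match several genes, the genome build and the annotation are not given in the sources used here. Counts of overlapping genes, of antisense partners and of near-identical copies may therefore share reads, and comS, a very short gene, is open to reads of a neighbouring transcript. The table listed 1959 genes, of which 1958 were named by a RefSeq protein accession and 1 by a symbol (comS). No rRNA gene was among the rows, and no column of the table was left unused.

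Both columns of the medium group carried the same header, so the table showed their group but not which culture each was. They are called media replicate A and media replicate B, and these letters pair them with nothing. The other 6 columns were matched to their samples by title.

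The gene table supplied as a reference describes another strain of the species under other protein accessions, and 0 of the 1959 rows matched it. The rows were therefore left without gene names, apart from comS. Before the data were examined, 32 gene lists with 249 entries had been fixed together with the rule for the genes to be named. That rule asked for the 10 genes that rose most and the 10 that fell most in each comparison with medium, among called genes with both treated libraries beyond both medium libraries, for the 5 highest and 5 lowest between additives, and for a set of competence, bacteriocin and adhesion genes. Of the list entries, 1 could be matched (comS), so the list tests (camera and fry) could not be run. Because unnamed accessions carry little meaning, the rule was reduced to the 2 genes that rose most and the 2 that fell most with MUC5B glycans relative to medium. NP_720935.1 is named as well, chosen after its values were seen, as the 1 gene called between the 2 glycan groups. The gene groups described by the size of their change were also defined after the values were seen.

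Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 1954 genes, and libraries were scaled with TMM factors, which lay between 0.93 and 1.05. One quasi-likelihood model with a mean for each of the 4 groups was fitted to all 8 libraries, with robust estimation of the spread, so that the groups shared 1 estimate of it. Each of 5 comparisons was tested with a two-sided quasi-likelihood F test, and p-values were adjusted over the 1954 genes with the Benjamini-Hochberg method. A gene is said to have risen, fallen or been called where its adjusted p was under 0.05. Fold changes are relative to TMM scaling. With total counts as the only scaling, the median log2 fold change of all genes moved by 0.11 for intact mucin, 0.14 for MUC5B glycans and 0.15 for MUC5AC glycans versus medium. Normalized CPM values were computed from the counts, the library totals and the TMM factors, and are given as mean ± SD over the 2 libraries.

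The total counts per library ran from 12848953 to 36254202. No 2 replicates of a group agreed within sampling noise, since chi-square per degree of freedom between them had a lowest value of 226. The procedure was tested on simulated counts with 200 genes changed in each group with an additive, and genes were drawn independently. For intact mucin versus medium, 52% of the 2-fold and 95% of the 4-fold changes were recovered among 1954 genes, with 2.65% of the calls false. For MUC5B glycans versus medium, 66% and 100% were recovered, with 6.21% of the calls false. For MUC5AC glycans versus medium, 58% and 96% were recovered, with 4.35% of the calls false. With fewer changed genes the adjusted threshold is stricter, so these shares may not hold for intact mucin versus medium. There 0 genes were called in the data, and comS, 3.74-fold lower, was among those not called.

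Overlaps and correlations between comparisons that share the medium libraries were set beside 50 simulations of unchanged groups. In the simulations all counts, those of medium included, were redrawn for each gene independently of the others. Alternatives planned before the data were examined were DESeq2 size factors within edgeR, total counts only, no filter on low counts, a minimum mean count of 50, DESeq2 1.42.0, limma-voom (limma 3.58.1), a fit of only the groups compared, a replicate block, leaving out each library in turn, and a 2-fold minimum. Thinning to the smallest library, leaving out both MUC5AC glycan libraries, a fit of the 6 libraries with an additive, and correlations with 1 medium library given to each comparison were added after the data had been seen.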

Results

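Transcript levels of Streptococcus mutans UA159, a bacterium of dental plaque, were measured by RNA sequencing after 2 h of growth in medium alone, with intact salivary MUC5B mucin, with the glycans of MUC5B in solution, or with the glycans of porcine MUC5AC in solution. Each group had 2 libraries. The total counts were 12848953 and 14501747 in media replicates A and B. They were 17316930 and 13371730 in intact mucin replicates 1 and 2, 36254202 and 16461427 in MUC5B glycan replicates 1 and 2, and 33808569 and 16635421 in MUC5AC glycan replicates 1 and 2. Of 1959 genes listed, 3 had no count in any library and 1954 were tested. The first principal component held 72.6% of the variance and separated the 4 glycan libraries from the 4 medium and intact mucin libraries. MUC5AC glycan replicate 2 stood apart from its partner, with a median absolute log2 difference of 0.396 over genes, against 0.121 to 0.168 within the other 3 groups.

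The response to the intact mucin was examined first. No gene passed the threshold between intact MUC5B and medium in edgeR's unpaired quasi-likelihood test with Benjamini-Hochberg adjustment, although 96 of 1954 genes had an unadjusted p under 0.05. The test kept a split between replicates, described below, in its spread, so 0 calls do not show that no gene changed. DESeq2 called 56 genes, of which 54 fell and 2 rose, and limma-voom called 0. The comS gene, which encodes the precursor of the XIP pheromone that switches on natural competence, was at 26.1 ± 5.47 CPM with the mucin and 97.6 ± 37.1 CPM in medium (SD, n = 2). Its log2 fold change was −1.90 (SE 0.32), a level 3.74-fold lower, with an edgeR adjusted p of 0.0950 over all genes. Its unadjusted edgeR p was 8.79e-04, which a value adjusted over the list alone would only repeat, since comS was the only list member matched.

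Genes that fell with MUC5B glycans had low values in the intact mucin libraries too. Of the 117 such genes, 114 (97.4%) had a negative log2 fold change in intact mucin versus medium, with a median of −0.77. In simulations in which intact mucin changed nothing, the shared medium libraries gave 56.8% and a median of −0.05. Genes were drawn independently there, so a deviation of the medium cultures shared by many of these genes was not covered. Both mucin libraries lay below both medium libraries for 111 of the 117 genes, and 80 had an unadjusted p under 0.05. The 20 genes that fell most with MUC5B glycans took 7.20 ± 0.82% of all counts in medium and 3.50 ± 0.11% with the intact mucin (SD, n = 2). Their log2 fold changes with the mucin lay between −1.28 and −0.996, and edgeR and limma-voom called 0 of them, 19 had an unadjusted edgeR p under 0.05, and DESeq2 called 16. These genes were chosen on these libraries and are not independent evidence of a direction. Without MUC5AC glycan replicate 1, replicate 2 or both of them, edgeR called 40, 41 and 41 genes, all of which fell and all of which were among the 117, while a fit of only the mucin and medium libraries called 0. The libraries also split on something other than their group. The Spearman correlation across genes was 0.992 between media replicate A and mucin replicate 1 and 0.995 between media replicate B and mucin replicate 2. Within the medium group it was 0.982, and within the mucin group 0.980. For some genes the split ran through the glycan groups too. An example picked after the values were seen is NP_720610.1. It was at 366 and 86.9 CPM in media replicates A and B and at 377 and 87.9 CPM in mucin replicates 1 and 2. With MUC5B glycans it was at 528 and 107 CPM, and with MUC5AC glycans at 479 and 105 CPM, in replicates 1 and 2. The unpaired test kept this split in its spread.

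With MUC5B glycans in solution, falls outnumbered rises. Relative to medium, 117 genes fell and 14 rose, and 105 of the falls and 10 of the rises were at least 2-fold. The comS transcript fell 14.2-fold to 6.82 ± 1.35 CPM (SD, n = 2), with a log2 fold change of −3.83 (SE 0.35, edgeR adjusted p = 8.48e-04). A set of 20 genes fell at least 16-fold, with a median log2 fold change of −8.04, and their share of all counts was 0.0611 ± 0.0033% with the glycans. The strongest fall was that of NP_722280.1, from 3156 ± 520 to 6.20 ± 0.38 CPM (SD, n = 2), which was 508-fold (edgeR adjusted p = 7.19e-05). NP_721054.1 fell 506-fold, from 10162 ± 1110 to 20.1 ± 1.34 CPM (SD, n = 2), with an edgeR adjusted p of 6.79e-06. The 117 genes that fell together took 18.1 ± 1.42% of all counts in medium and 2.39 ± 0.20% with MUC5B glycans.

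The genes that rose did so by smaller factors, with a median log2 fold change of 1.74 and a highest value of 2.56. NP_721840.1 rose 5.92-fold, from 8.05 ± 0.56 to 47.6 ± 5.15 CPM (SD, n = 2, edgeR adjusted p = 0.0014). NP_721843.1 rose 5.27-fold, from 11.3 ± 1.02 to 59.6 ± 6.33 CPM (SD, n = 2, edgeR adjusted p = 6.27e-04). The number of calls was 131 in all. It was 225 with DESeq2 (27 rises and 198 falls), and 127 with total counts as the only scaling (23 rises and 104 falls). A fit of these 2 groups alone gave 161 (11 rises and 150 falls). Leaving out both MUC5AC glycan libraries, which are in neither of the groups compared, gave 224 (44 rises and 180 falls).

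**Figure D1:**
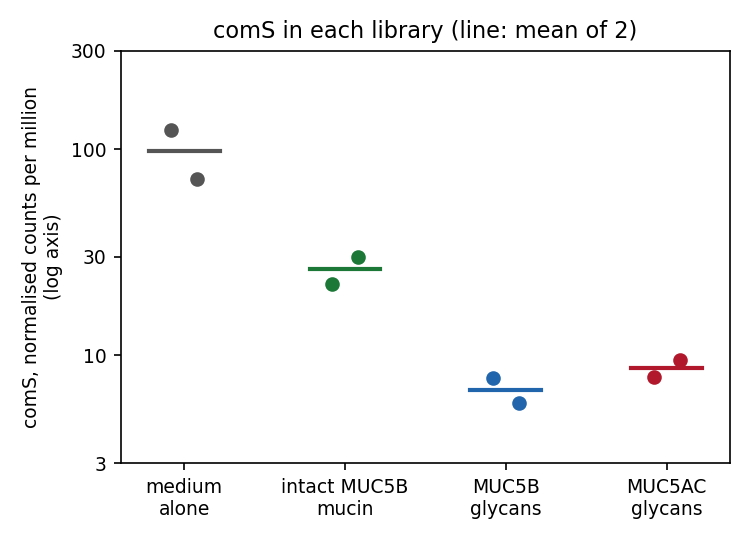
Normalised CPM of comS (log axis) in each of the 8 libraries, with 1 point per library and a line at the mean of the 2 libraries of a group. Means were 97.6 in medium, 26.1 with intact mucin, 6.82 with MUC5B glycans and 8.70 with MUC5AC glycans.

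With porcine MUC5AC glycans, from another mucin and another species, falls again outnumbered rises. Relative to medium, 144 genes fell and 45 rose, and 129 of the falls and 12 of the rises were at least 2-fold. The comS transcript fell 11.2-fold to 8.70 ± 1.16 CPM (SD, n = 2), with a log2 fold change of −3.49 (SE 0.35, edgeR adjusted p = 0.0012). NP_722280.1 fell 275-fold to 11.4 ± 5.82 CPM (edgeR adjusted p = 1.03e-04) and NP_721054.1 fell 236-fold to 43.1 ± 7.46 CPM (edgeR adjusted p = 1.16e-05). NP_721840.1 rose 6.22-fold (edgeR adjusted p = 0.0012) and NP_721843.1 rose 5.12-fold (edgeR adjusted p = 6.67e-04). With total counts as the only scaling, 210 genes rose and 143 fell, so that the share of rises was 59.5% in place of 23.8%. The total of 189 calls was 339 with DESeq2, 112 in a fit of these 2 groups alone (7 rises), 101 and 107 without media replicates A and B (6 and 4 rises), and 813 without MUC5AC glycan replicate 1, which left replicate 2 alone in its group. The rises also numbered 10 without intact mucin replicate 1 or 2, and 24 and 13 without MUC5B glycan replicates 1 and 2. Of the 813 genes, 432 rose and 381 fell, so that falls no longer outnumbered rises.

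The falls were largely shared between the glycan groups. Of the called genes, 107 fell with both glycan preparations, against 8.62 for independent lists. The genes that rose with both numbered 11, against 0.322 for independent lists, and 0 genes were called in opposite directions. Simulations of unchanged groups, which redrew the medium counts, gave means of 0 shared falls and 0.04 shared rises. Few genes pass the threshold where nothing changed, so these means do not show how far the shared medium libraries raise the overlap. The count of shared rises was 5 and 4 without media replicates A and B, 7 without MUC5B glycan replicate 2, and 60 and 22 without MUC5AC glycan replicates 1 and 2. Across genes, which are not independent replicates, the log2 fold changes of both glycan groups had a Pearson correlation of 0.93 against 0.51 in the simulations, and a covariance of 0.978 against 0.057. For intact mucin and MUC5B glycans the correlation was 0.69 against 0.51 and the covariance 0.190 against 0.058. For intact mucin and MUC5AC glycans the correlation was 0.69 against 0.51 and the covariance 0.193 against 0.057. With 1 medium library given to each comparison, in both ways, so that none was shared, the covariance was 0.925 and 0.950 for both glycan groups, 0.139 and 0.167 for intact mucin and MUC5B glycans, and 0.128 and 0.182 for intact mucin and MUC5AC glycans. The correlation was then 0.840 and 0.882 for both glycan groups. It was 0.361 and 0.522 for intact mucin and MUC5B glycans, and 0.322 and 0.561 for intact mucin and MUC5AC glycans. No simulation without shared libraries was run beside these values. Intact mucin versus medium had 0 calls in edgeR's main fit and in limma-voom. The overlap of calls with all 3 additives was therefore fixed at 0 in both, and says nothing about sharing. No gene was called in the same direction with all 3 additives by edgeR, nor by limma-voom, while DESeq2 called 54, and edgeR called 40 and 41 without MUC5AC glycan replicates 1 and 2.

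**Figure D2:**
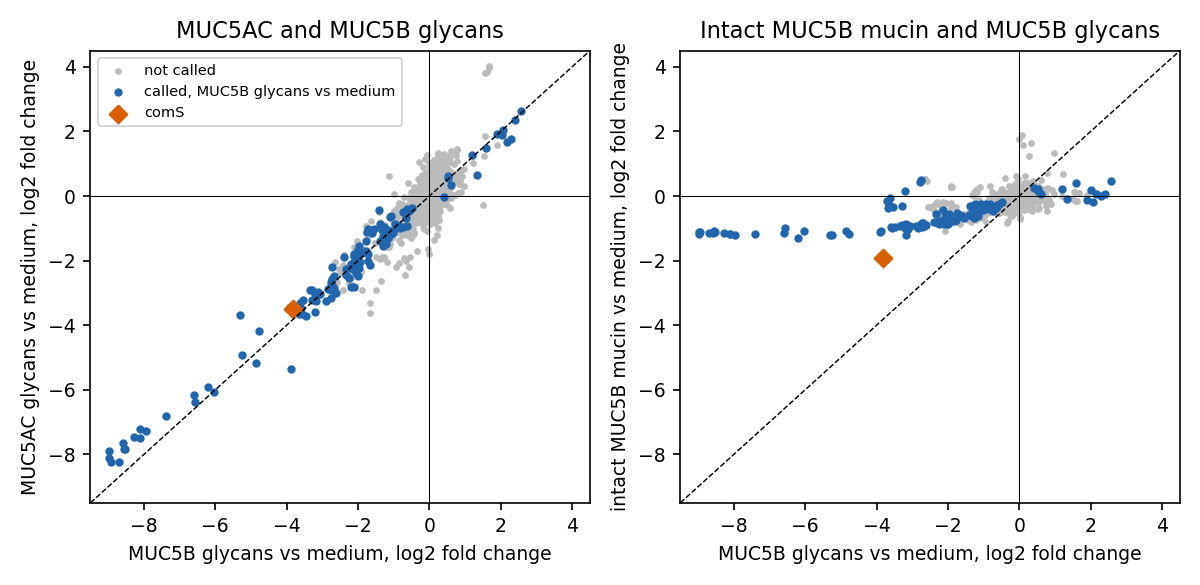
Log2 fold changes versus medium of the 1954 genes tested, with 1 point per gene, for MUC5AC glycans (left, vertical axis) and intact MUC5B mucin (right, vertical axis) against MUC5B glycans (horizontal axes). The dashed line marks equal values, blue points are the 131 genes called with MUC5B glycans, and the 20 strongest falls lie near a log2 fold change of −1.14 with the intact mucin.

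The intact mucin was then compared directly with its own glycans. Relative to MUC5B glycans, 80 genes were higher and 9 were lower with the intact mucin in edgeR's test, and 87 of these 89 differed at least 2-fold. All 20 of the strongest falls were called, with a median log2 difference of 6.83, and 79 of the 117 genes that had fallen were called in all. These genes were chosen for low values in the same MUC5B glycan libraries, so their calls are not independent evidence. NP_721054.1 was at 4671 ± 70.8 CPM with the mucin and 20.1 ± 1.34 CPM with the glycans (SD, n = 2, edgeR adjusted p = 1.44e-05), and NP_722280.1 was at 1408 ± 12.0 and 6.20 ± 0.38 CPM (SD, n = 2, edgeR adjusted p = 1.58e-04). NP_721843.1 was 5.05-fold lower with the mucin (edgeR adjusted p = 0.0010) and NP_721840.1 was 4.28-fold lower (edgeR adjusted p = 0.0042). The comS transcript was 3.79-fold higher with the mucin (log2 difference 1.92, SE 0.33, edgeR adjusted p = 0.0240). That call was lost with limma-voom (adjusted p = 0.0671) and in edgeR without intact mucin replicate 2 (0.1226), MUC5B glycan replicate 1 (0.1129) or MUC5B glycan replicate 2 (0.1471), while 15 of 19 alternatives kept it and adjusted p ran from 4.73e-07 to 0.1471. DESeq2 called 148 genes, of which 130 were higher and 18 lower with the intact mucin. Without both MUC5AC glycan libraries, edgeR called 127, of which 111 were higher and 16 lower.

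**Figure D3:**
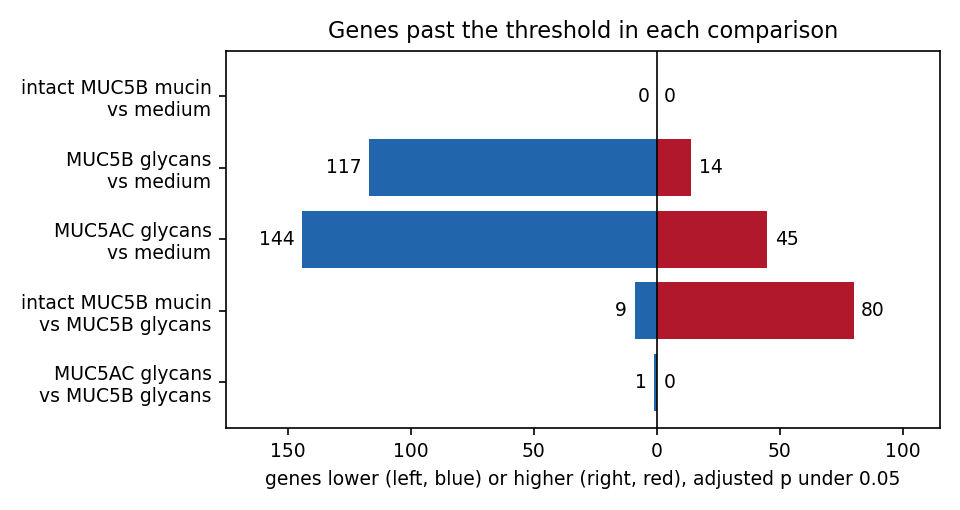
Number of genes past an adjusted p of 0.05 in each of the 5 comparisons (edgeR, 1954 genes tested), drawn to the left of 0 for genes lower in the group named first and to the right for genes higher in it. Falls outnumber rises for both glycan groups versus medium, 117 to 14 and 144 to 45.

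Between the glycans of MUC5AC and of MUC5B, 1 gene was called by edgeR, while 167 had an unadjusted p under 0.05, DESeq2 called 26 and limma-voom called 1. NP_720935.1 was at 164 ± 11.2 CPM with MUC5AC glycans and 569 ± 13.3 CPM with MUC5B glycans (SD, n = 2), which was 3.46-fold lower (log2 difference −1.79, SE 0.11, edgeR adjusted p = 0.0039). Its level in medium was 569 ± 28.3 CPM, from which it differed with MUC5AC glycans (edgeR adjusted p = 1.41e-04). The comS level did not differ detectably, with a log2 difference of 0.34 and a 95% interval of −0.45 to 1.13. The 20 strongest falls with MUC5B glycans had a median log2 difference of 0.64, higher with MUC5AC glycans, and 2 of them were lower. They were chosen for low values with MUC5B glycans, which favours this direction. Of the 117 genes that fell with MUC5B glycans, 16 had an unadjusted edgeR p under 0.05 between the glycans. Of the 117, edgeR and limma-voom called 0 and DESeq2 called 6, all 6 higher with MUC5AC glycans. Without MUC5AC glycan replicate 1 or 2, edgeR called 22 and 1 of them. Across genes, MUC5AC glycan replicate 1 had a Spearman correlation of 0.993 with MUC5B glycan replicate 1 and of 0.951 with MUC5AC glycan replicate 2. The comparison depended on which libraries entered it, with 688 calls without MUC5AC glycan replicate 1, 4 without replicate 2, and 0 without MUC5B glycan replicate 1 or 2. The call of NP_720935.1 was lost without MUC5B glycan replicate 1 or 2 (edgeR adjusted p = 0.0635 and 0.0657) and in a fit of these 2 groups alone (edgeR adjusted p = 0.3420).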

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

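Thinning to the smallest library, the fits without both MUC5AC glycan libraries, the fit of the 6 libraries with an additive and the correlations with 1 medium library were chosen after the data had been seen. With 2 libraries per group, the count of calls moved with the test and with single libraries, and the cause was not tested. DESeq2 gave 56 calls for intact mucin versus medium, 225 for MUC5B glycans, 339 for MUC5AC glycans, 148 for mucin versus MUC5B glycans and 26 between the glycans, and it gave 166 falls and 17 rises shared by both glycans and 54 genes with all 3 additives. Without both MUC5AC glycan libraries, 41 genes were called with intact mucin and 224 with MUC5B glycans. With total counts only, 353 genes were called with MUC5AC glycans and 18 rose with both glycans. In a fit of only the groups compared, the calls were 112 with MUC5AC glycans, 0 between the glycans and 7 for shared rises. Between the glycans, DESeq2 size factors gave 3 calls and thinning gave 4. Leaving out 1 library at a time gave 0 to 41 calls with intact mucin, 86 to 279 with MUC5B glycans, 101 to 813 with MUC5AC glycans, 64 to 129 for mucin versus MUC5B glycans, 0 to 688 between the glycans, 4 to 60 shared rises and 0 to 41 genes with all 3 additives. A library left alone in its group was assumed to vary like the others.

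Over the 6 named genes, 286 of 305 values under alternatives kept their direction and side of the threshold, 8 lost the call, 9 gained it and 2 changed sign. Both were of NP_721843.1 with intact mucin, which was not called and ranged from −0.029 to 0.154 with 1 library left out. For intact mucin versus medium, comS ranged from −2.25 to −1.45 and passed the threshold in 1 of 17 alternatives (DESeq2 adjusted p = 3.11e-06, range 3.11e-06 to 0.7885). The median of the 20 strongest falls with intact mucin was −1.03 with total counts, −1.01 without media replicate A and −1.26 without media replicate B. The comS counts were 101 to 1480 per library.

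No paired analysis was run for the comparisons with medium, because both medium columns carry the same header and so no number of their own. A block under each way of assigning the medium columns was not fitted. For the other comparisons, no label says that the numbers mark a shared batch. With a replicate block in the 6 libraries with an additive, 105 genes were called for mucin versus MUC5B glycans, against 71 without it, and 0 between the glycans, against 1, where NP_720935.1 had an adjusted p of 0.1042 with the block and 0.0385 without it. The correlations of same-numbered deviations were 0.71, 0.17 and 0.36 for mucin with MUC5B glycans, mucin with MUC5AC glycans and both glycans. The gene lists were not run, since 1 of 249 entries matched, nor the alternative with rRNA genes, since the table has none.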

Other observations

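The tests in this part were chosen after the fold changes had been seen, and only the outcome predicted for thinning was written before its result. Many genes that fell with MUC5B glycans stood at consecutive accession numbers, and 98 of the 117 were in stretches of 2 or more. The longest stretch held 10 genes, which fell by a median of 12.0-fold with MUC5B glycans and 9.61-fold with MUC5AC glycans. With intact mucin their median log2 fold change was −0.22, between −0.36 and 0.50, with no unadjusted p under 0.05. All 10 were called between intact mucin and MUC5B glycans, but they were chosen on the same glycan libraries. A stretch of 9 genes that held 4.89 ± 0.54% of all counts in medium (SD, n = 2) fell by a median of 277-fold and 175-fold with the MUC5B and MUC5AC glycans, and lay at a median log2 value of −1.14 with intact mucin. Another stretch of 9 fell by medians of 6.54-fold and 7.41-fold, and a stretch of 5 by 6.42-fold and 5.56-fold. Among the rises, 1 stretch of 7 genes rose by medians of 4.48-fold and 3.81-fold, and these 7 genes had a median log2 fold change of 0.06 with intact mucin.

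Some stretches with large fold changes were not called by edgeR. A run of 4 consecutive accessions summed to 8094 CPM in MUC5AC glycan replicate 2 and to 661 CPM in replicate 1, against 268 and 311 CPM in media replicates A and B and 573 and 1217 CPM in MUC5B glycan replicates 1 and 2. Their log2 fold changes with MUC5AC glycans lay between 3.81 and 4.04, with edgeR adjusted p between 0.0621 and 0.0852, and DESeq2 called all 4. Another run of 5 summed to 338 and 127 CPM in intact mucin replicates 1 and 2, against 80.4 and 60.6 CPM in media replicates A and B. Their log2 fold changes with intact mucin lay between 1.23 and 1.88, with edgeR adjusted p between 0.328 and 0.974, and DESeq2 called 2 of the 5.

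More genes were called with MUC5B glycans than with the intact mucin. Greater depth of the glycan libraries is argued against, since thinning every library to the smallest total left 130 calls with MUC5B glycans. A spread raised by MUC5AC glycan replicate 2 would not account for the whole difference. Without both MUC5AC glycan libraries, 41 genes were called with the intact mucin and 224 with MUC5B glycans. Whether that replicate in particular raised the spread was not tested. The form in which the mucin was given, which the design names, stays open, and the direct comparison of intact mucin with its glycans called 89 genes in edgeR.

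The 20 strongest falls lay near 1 common factor in the intact mucin libraries, 2.21-fold below medium. Admixture of glycan library RNA is argued against, since a share of 45.3% of medium-like RNA would raise the genes that rose with MUC5B glycans to a median log2 fold change of 1.19, and they had 0.12 (SD 0.19 over 14 genes). A set of 18 genes was chosen without the medium libraries, as called and at least 16-fold higher with intact mucin than with MUC5B glycans. It had a median of −1.14 and a highest value of −0.996, the same as the 20 genes. None of the other 97 genes that fell could enter it, since their highest log2 difference was 3.56. It is therefore not a second, separate set. It shows only that choosing without the medium libraries left the value unchanged. Chance was not settled, since the 18 genes were still compared with those libraries. A deviation shared by these genes there would give the same values. A mix of medium-like and glycan-like cells follows the same arithmetic as the admixture, so the genes that rose argue against it too. Lower values with intact mucin were not confined to the 20 genes. The other 97 genes that fell with MUC5B glycans had a median log2 fold change of −0.64 with the mucin. For 91 of these 97, both mucin libraries lay below both medium libraries, but the longest stretch of 10 genes had a median of only −0.22. A smaller share of cells running a program that holds the 20 genes, but not the genes that rose, remains a candidate explanation. RNA from whole cultures cannot tell it from an equal drop in every cell. The slope of the mucin on the glycan log2 fold changes was −0.0056 (SE 0.0094). That SE takes the 20 genes as independent, which genes from the same libraries and at consecutive accession numbers need not be. A slope near 0 goes with both, so it does not decide.

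The placement of the falls at consecutive accession numbers was set against chance placement. There were 70 adjacent pairs among the 117 genes, against a mean of 6.91 and a highest value of 21 in 100000 permutations (one-sided permutation p = 0.00001, the smallest they can give). As a hypothesis, the falls may follow operons, but no map of the genome tied the accessions to positions here, so this was not tested.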
